A study of Caenorhabditis elegans with 6 samples.

How the data were processed

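RNA from whole C. elegans larvae was measured in 6 libraries, 3 of the strain hs::control and 3 of the strain hs::lin-29. Per the labels' protocols, RNA was extracted with the Zymo Quick-RNA kit and libraries were made with the NEBNext Ultra RNA kit. The deposited values are raw counts of reads per gene, made by the authors and not normalized, with 1 table per library. The submitters' processing notes name bcl2fastq 2.18, STAR 2.5.2b, HTSeq 0.6.1p1, DESeq2 1.12.3, R 3.3.2 and the genome build ce10, without their roles. The annotation release and the strand setting are not given in the sources used here. The reference used here, WBcel235, is another build, so no coordinates are given, and it served only for gene names, the number of annotated transcripts per gene and overlaps between genes.

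Each table lists 41573 gene names, of which 38131 were found in the gene name table; of the 13045 tested, 11220 were. Rows that name no gene took 39.7% to 41.8% of the counts per library, made of reads outside genes (10.8% to 12.4%), ambiguous reads (10.7% to 11.3%) and reads with several alignments (17.0% to 19.2%), and stayed out of library sizes and tests. Such counting leaves out reads shared between near-identical genes, so members of the collagen, histone and F-box families can be undercounted. If counting ignored strand, reads of overlapping genes cannot be told apart: of lin-29 and the 24 genes with the largest changes, 8 overlap another annotated gene, namely lin-29, col-138, col-124, bli-1, bli-2, Y45G12C.1, prx-11 and F21A3.11, and 1 was not matched. Of 17365 protein-coding genes matched by name, 1954 are listed at 0 in every library, so a listed 0 is not read as absence.

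Genes were kept by filterByExpr of edgeR 4.0.16 at its defaults (a minimum count of 10 scaled to library size and a total of 15). Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test with robust estimation, two-sided, with strain as the only term and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0215, a biological coefficient of variation of 14.7%. Standard errors were taken as the absolute log2 fold change divided by the square root of F and are approximate. Between replicates of a strain the counts differed by far more than sampling noise (chi-square per degree of freedom 10.2 or more), so no 2 libraries were treated as 1 sample.

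Gene lists were written before the data were examined, and 31 of them with at least 5 tested genes were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a correlation of 0.01 between genes. A list of mitochondrially encoded genes matched no name and was not used here. The genes named in the text follow a rule set at the same time: lin-29 in every library; the 12 higher and 12 lower with the largest change among those with an adjusted p under 0.05, a mean of at least 5 CPM and non-overlapping libraries, lin-29 left out; for each list up to 4 members past the threshold with at least 1 CPM by size of change, or where none passed the 2 with the smallest p; and all stage collagens and heterochronic genes. Genes named outside this rule are said to be so.

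The test was tried on simulated counts for the 13045 genes of the comparison of hs::lin-29 with hs::control, with 200 genes changed. edgeR recovered 36% of the genes changed 1.5-fold, 74% at 2-fold, 84% at 4-fold and 94% at 8-fold, and 8 of its calls were false (5.26%). DESeq2 made 22 false calls (12.6%) and limma-voom 7 (4.70%), so calls by DESeq2 alone are less certain. Each gene was drawn independently, so correlation between genes was not simulated. The alternatives were other scalings, other filters on low counts, the DESeq2 1.42.0 Wald test, limma-voom, a test without robust estimation, the 20 most abundant genes left out, a replicate block, each library left out in turn, camera with an estimated correlation and fry. Counts of genes past the threshold in 4 lists, under each refit, were added after the data were seen. R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.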

Results

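Whole larvae of the nematode Caenorhabditis elegans were profiled by RNA sequencing, with 3 libraries from a strain named hs::lin-29 and 3 from a strain named hs::control. Synchronized animals were grown at 20 °C, heat-shocked in the L3 stage at 28 h after feeding for 30 min at 37 °C, and sampled 1 h later. By the stated design the heat shock is meant to induce lin-29 in the hs::lin-29 strain, and the series holds no library without heat shock. LIN-29 is a zinc finger transcription factor at the end of the heterochronic pathway, which times the switch of the skin from larval to adult fates. Each library is a table of read counts per gene, with between 14553652 and 17303509 counts assigned to genes. The libraries are named here by strain and replicate number, and levels are CPM (counts scaled to the library total with TMM factors), as mean ± SD over 3 libraries.

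The series has the stated aim of finding LIN-29 target genes, and its 1 comparison sets hs::lin-29 against hs::control after the same heat shock. Cuticle collagen genes of a fixed list were 10 of the 12 largest rises and 34 of all 321 genes that rose: bli-6, col-38, col-138 and col-139 went from 10.5 CPM or less to between 472 and 2418 CPM, and col-19, a collagen used as a mark of the adult cuticle, rose 52.5-fold (log2 fold change 5.72, SE 0.46, 3 libraries per strain). The lin-29 cofactor gene mab-10 rose 2.53-fold (log2 fold change 1.34, SE 0.17), while the other 11 heterochronic genes tested did not pass the test. Among the genes that fell were the nuclear receptor gene nhr-80 (log2 fold change -2.73, SE 0.14), the fatty acid elongase genes elo-5 and elo-6, genes for peroxisomal fatty acid breakdown and the epidermal antimicrobial peptide genes nlp-30 and nlp-31. The RNA comes from the whole body, so a level is an average over all tissues.

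The gene lin-29 itself was examined first. It stood at 49.8, 43.8 and 45.8 CPM in hs::control replicates 1 to 3 and at 131, 517 and 339 CPM in hs::lin-29 replicates 1 to 3. The rise was 7.08-fold, a log2 fold change of 2.82 with a standard error (SE) of 0.41, and passed edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p of 0.004621. Reads of the transgene and of the chromosomal gene are not told apart in these counts. Without a filter on low counts the log2 fold change was 2.83 and the adjusted p 0.1017, in a range of 8.161e-06 to 0.1017 over all alternatives run.

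Of 13045 genes tested, 861 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 321 higher and 540 lower in hs::lin-29. This is 6.60% of the genes tested, the share beside which the counts in gene lists below stand. At 2-fold or more there were 182 higher and 252 lower, and at 4-fold or more 82 higher and 48 lower, so the largest changes were mostly rises. In all 861 the libraries of one strain lay entirely above those of the other, as they did in 3031 of all tested genes (23.2%, where chance gives 10%). The count was 490 without hs::control replicate 2, 459 without hs::control replicate 3 and 547 without hs::lin-29 replicate 3. Genes higher then numbered 162, 135 and 210 and genes lower 328, 324 and 337, and genes lower numbered 352 without hs::lin-29 replicate 2. The labels call the replicates trials and do not say whether these were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

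Of the 12 largest rises, 10 were cuticle collagen genes on a list written before the data were examined. bli-6 rose 593-fold, from 1.34 ± 0.982 to 761 ± 114 CPM (log2 fold change 9.21, SE 0.38, adjusted p 1.496e-05 by edgeR). col-38 rose 234-fold, from 10.5 ± 5.50 to 2418 ± 168 CPM, the highest level reached among the 12. col-138 rose 196-fold to 836 ± 171 CPM, col-139 130-fold to 472 ± 233 CPM, col-140 103-fold to 534 ± 278 CPM and col-124 103-fold to 768 ± 277 CPM. col-49 rose 89.5-fold, from 2.51 ± 0.856 CPM in hs::control, and col-60 70.5-fold, from 0.434 ± 0.242 CPM. bli-1 and bli-2, whose products form the struts of the adult cuticle, rose 81.4-fold to 269 ± 97.2 CPM and 56.8-fold to 320 ± 137 CPM. The 12 were completed by rol-1, a gene named for a rolling body shape, and by E01G4.6. rol-1 rose 88.4-fold, from 1.54 ± 1.15 CPM in hs::control, and E01G4.6 rose 71.1-fold. Neither is on that list, which does not mean that they are not collagen genes. The adjusted p by edgeR was 0.0008044 or less for each of the 12.

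**Figure D1:**
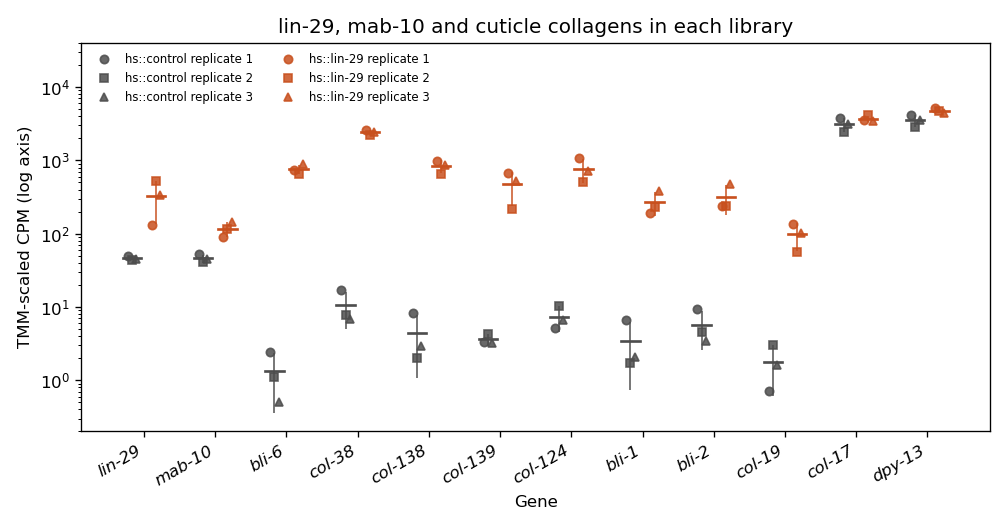
TMM-scaled CPM on a log axis for lin-29, mab-10 and 10 collagen genes; each point is 1 library, grey for hs::control and orange for hs::lin-29, horizontal bars are means and vertical lines are 1 SD either side. The collagen genes from bli-6 to col-19 stand apart by more than 10-fold, from 1.34 against 761 CPM for bli-6 to 1.80 against 98.5 CPM for col-19, while the strains overlap for col-17.

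Across the 140 cuticle collagen genes tested, 34 rose, 4 fell and 102 did not pass over all genes tested; adjusted over the list alone the counts were 46 and 7. Of the 34 that rose, 19 did so 10-fold or more, and the median rise was 19.1-fold. Of those 19, 13 had a mean below 5 CPM in hs::control, so the size of their fold change is uncertain. Over all 140 genes the median log2 fold change was 0.26. The 4 that fell, named here after their values were seen, were col-158 (log2 fold change -2.88, SE 0.42), col-146 (-1.54, SE 0.16), col-46 (-0.84, SE 0.14) and col-169 (-0.46, SE 0.11). The count of collagens that fell was 7 with DESeq2 and 8 without hs::lin-29 replicate 1. The list passed camera at an adjusted p of 6.15e-07, with p = 0.145 and an adjusted p of 0.9351 when the correlation between genes was estimated. Of hs::control, replicate 1 stood apart on the second principal component (45.7 against -21.4 and -17.7), and without it 33 collagens rose and 3 fell.

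Of 7 tested collagens chosen as marks of larval or adult stages, all of them on the wider list too, bli-1, bli-2 and col-19 rose. col-19 went from 1.80 ± 1.19 to 98.5 ± 40.8 CPM (log2 fold change 5.72, SE 0.46, adjusted p 0.0002512 by edgeR). The other 4 did not pass over all genes, and adjusted over the list alone 4 of the 7 rose. Their log2 fold changes were 0.44 for dpy-13, 0.24 for col-17, -0.05 for sqt-1 and -0.31 for rol-6. dpy-13 was past the threshold with DESeq2 (adjusted p 0.04616), with no filter on low counts (0.014) and without hs::control replicate 1 (0.04708), while over the alternatives run its adjusted p ran from 0.014 to 0.3876. The list passed camera at an adjusted p of 0.002977, with p = 0.0385 and an adjusted p of 0.9351 with an estimated correlation. col-7, another collagen used as an adult mark, had at most 2 counts in any library and was not tested.

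Of 12 heterochronic genes tested, mab-10 alone rose and none fell, the same count as adjusted over the list alone. mab-10, which encodes a cofactor that binds LIN-29, went from 46.2 ± 5.83 to 117 ± 26.6 CPM (log2 fold change 1.34, SE 0.17, adjusted p 0.00248 by edgeR). The LIN-29 repressor gene lin-41 stood at 200 ± 17.7 and 187 ± 30.8 CPM (log2 fold change -0.10, SE 0.14). lin-14, which acts early in the pathway, stood at 2.84 ± 0.339 and 2.92 ± 0.512 CPM. The other values ran from a log2 fold change of -0.53 for lin-46 (SE 0.17) to 0.15 for lin-42 (SE 0.14), with dre-1 (-0.17), ain-1 (-0.14), blmp-1 (-0.10), alg-1 (-0.05), lin-59 (-0.04), apl-1 (0.06) and alg-2 (0.13) in between. lin-46 passed only with no filter on low counts (adjusted p 0.03504, in a range up to 0.3418 over all alternatives). The heterochronic genes hbl-1, daf-12, ain-2, kin-20 and lin-66 are listed at 0 in every library, as are some genes that most cells use. No level is read from them. lin-28 had at most 4 counts in any library and was not tested.

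**Figure D2:**
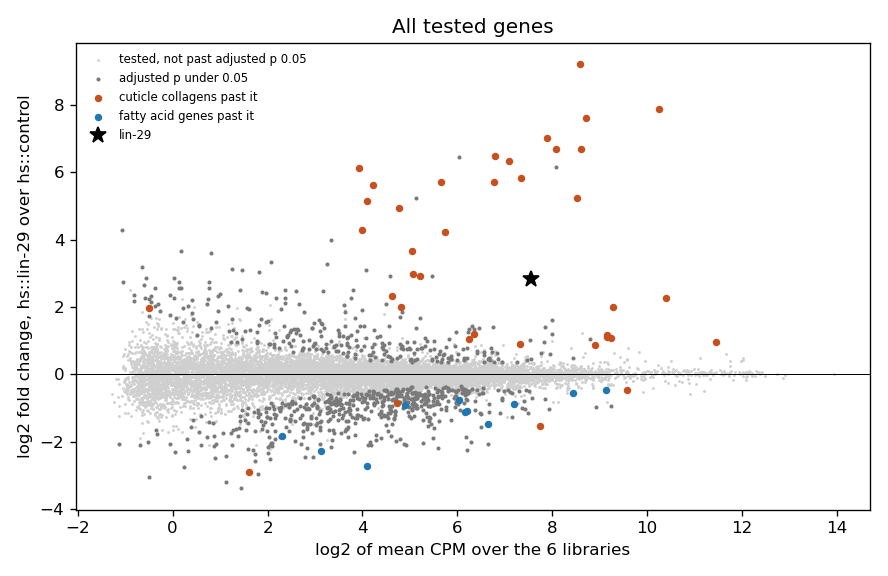
log2 fold change of hs::lin-29 over hs::control against the log2 of mean CPM over the 6 libraries, with 1 point per tested gene; dark grey marks the 861 genes past an adjusted p of 0.05, orange the cuticle collagens among them, blue the fatty acid genes among them and the star lin-29. The collagens that rose reach a log2 fold change of 9.21 and the fatty acid genes lie below 0, down to -2.73 for nhr-80.

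Among genes with a mean of at least 5 CPM the largest fall was that of nhr-80, which encodes a nuclear receptor that controls fatty acid desaturation. It went from 29.8 ± 3.13 to 4.48 ± 0.390 CPM, 6.64-fold lower (log2 fold change -2.73, SE 0.14, adjusted p 3.388e-05 by edgeR). Of the other 11 largest falls, btb-9 fell 5.47-fold, hacd-1, which encodes a hydroxyacyl-CoA dehydrogenase, 4.82-fold and prx-11, a peroxisome biogenesis gene, 4.29-fold. The remaining 8 have only sequence names, R05H10.1, W08E12.6, Y75B8A.4, F35E12.9, Y45G12C.1, Y69A2AL.2, F21A3.11 and C29F3.3. They fell between 5.44-fold for R05H10.1 and 4.25-fold for C29F3.3. Y75B8A.4, with the highest level of the 12, fell 4.71-fold (log2 fold change -2.24, SE 0.12).

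Of 18 fatty acid synthesis genes tested, none rose and 5 fell; adjusted over the list alone 6 fell. Besides nhr-80 these were the elongase genes elo-6, from 147 ± 23.6 to 52.7 ± 5.96 CPM (2.78-fold lower), and elo-5, from 98.3 ± 26.6 to 45.2 ± 7.38 CPM (2.17-fold lower), and dgat-2, an acyltransferase gene of fat storage, from 101 ± 17.2 to 47.3 ± 4.03 CPM (2.13-fold lower). The 5th, sbp-1, the worm's SREBP gene, fell 1.68-fold and is named after its values were seen. Over the 18 genes the median log2 fold change was -0.16. Their summed CPM overlapped between strains, at 2937 to 3685 in hs::control and 2622 to 3197 in hs::lin-29. Of the same list, fat-3, fat-4, fat-6, elo-1, elo-7, elo-8, pod-2, let-767 and acl-6 are listed at 0 in every library and so were not measured. The list passed camera at an adjusted p of 0.005964, with p = 0.289 and an adjusted p of 0.9351 with an estimated correlation. Without hs::control replicate 1 camera gave the list an adjusted p of 0.1146, in a range of 0.0003928 to 0.1146 over the scalings, filters, block and left-out libraries, and 5 of its genes fell.

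Of 22 genes of fatty acid breakdown tested, none rose and 6 fell; adjusted over the list alone 1 rose and 8 fell. hacd-1 went from 14.5 ± 5.70 to 3.00 ± 0.305 CPM. The enoyl-CoA hydratase family gene ech-8 fell 1.87-fold and maoc-1, of peroxisomal breakdown, 1.83-fold (log2 fold change -0.87, SE 0.13). ech-9 fell 3.51-fold with an adjusted p of 0.0441 by edgeR, a call lost without hs::control replicates 2 or 3 and without hs::lin-29 replicates 1 or 2 (adjusted p up to 0.153, range over all alternatives 0.0009089 to 0.211). Camera gave the list an adjusted p of 0.09833, and p = 0.216 and an adjusted p of 0.9351 with an estimated correlation. Of the same list, acdh-1, acdh-2, acdh-11, acdh-12, acox-1, cpt-2, lipl-5 and nhr-49 are listed at 0 in every library and so were not measured. Fatty acid genes are active in the intestine among other tissues, and of 20 intestine markers elt-2 alone passed, rising 2.69-fold (4 markers passed with DESeq2), while 15 of the 20 had a log2 fold change below 0, with a median of -0.12. Camera gave the intestine markers an adjusted p of 0.1218, and 0.01128 (lower) without hs::control replicate 3, in a range of 0.01128 to 0.6493 over the alternatives. With an estimated correlation camera gave the markers p = 0.416 and an adjusted p of 0.9351.

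**Figure D3:**
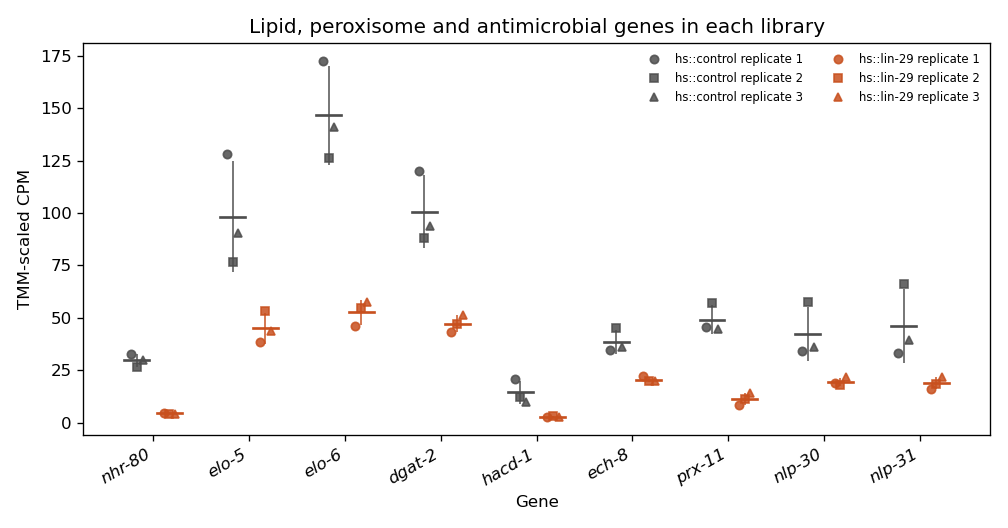
TMM-scaled CPM on a linear axis for 9 genes of lipid metabolism, peroxisomes and epidermal antimicrobial peptides; each point is 1 library, grey for hs::control and orange for hs::lin-29, horizontal bars are means and vertical lines are 1 SD either side. For each gene the 3 hs::lin-29 libraries lie below the 3 hs::control libraries, as for elo-6 at 52.7 against 147 CPM.

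Of 19 epidermal antimicrobial genes tested, none rose and 4 fell; adjusted over the list alone 7 fell. nlp-31 went from 46.3 ± 17.6 to 18.9 ± 2.86 CPM, 2.46-fold lower, and nlp-30 from 42.6 ± 12.9 to 19.6 ± 1.91 CPM, 2.17-fold lower. hmit-1.1, an osmolyte transporter gene, fell 2.04-fold and snf-12, a transporter gene needed to induce these peptides, 1.51-fold. The summed CPM of the 19 genes was 1923 in hs::control replicate 2, against 1272 and 1320 in the other hs::control libraries and 1056 to 1248 in hs::lin-29. The list passed camera at an adjusted p of 0.0001209, with p = 0.14 and an adjusted p of 0.9351 with an estimated correlation. The calls were lost for snf-12 without hs::control replicates 1 or 3 and hs::lin-29 replicates 2 or 3 (adjusted p up to 0.104, range over all alternatives 0.004108 to 0.1043) and for nlp-31 without hs::lin-29 replicates 1 or 2 (up to 0.054, range 8.754e-06 to 0.1764), and without hs::lin-29 replicate 2 the list held 2 falls.

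Of 43 hedgehog-related genes, many of them active in the skin, 3 rose and 1 fell, the same counts as adjusted over the list alone. grl-14 rose 7.59-fold, from 10.2 ± 1.54 to 77.9 ± 14.8 CPM (adjusted p 3.94e-05 by edgeR), grd-11 by 2.26 on the log2 scale (SE 0.30) and wrt-6 2.67-fold. grl-21 fell 1.70-fold, a call lost without hs::lin-29 replicate 3 (adjusted p 0.0527, range over all alternatives 9.748e-06 to 0.05273). In the Wnt list of 20 genes, dsh-2 rose 1.85-fold and apr-1 1.47-fold, the latter lost without hs::control replicate 2 (adjusted p 0.0515, range over all alternatives 0.0002237 to 0.05148), and adjusted over the list alone the count was 2 as well. The fusogen gene aff-1 (1.80-fold) and the nuclear receptor gene nhr-25 (log2 fold change 0.58) rose among 17 regulators of seam and hypodermis, and adjusted over that list alone 2 rose and 3 fell. The calls of aff-1 and nhr-25 were each lost without 5 of the 6 libraries, all but hs::lin-29 replicate 1 for aff-1 and all but hs::control replicate 1 for nhr-25 (adjusted p up to 0.16 and 0.132, ranges over all alternatives 0.000647 to 0.1597 and 0.0002565 to 0.1324).

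Molting and furrow genes showed few calls. Of 26 molting genes nhr-25 alone rose, and adjusted over the list alone none did. Of 5 furrow collagens none passed in either count, at an unadjusted p of 0.05 in edgeR, in DESeq2 or in limma-voom. Those with the smallest p were dpy-7 and dpy-9, at log2 fold changes of -0.36 and -0.28. The furrow collagen dpy-10 and the molting gene nhr-23 are listed at 0 in every library and so were not measured. Of 13 collagen processing genes tsp-15 fell 1.40-fold, of 37 cuticlin and zona pellucida genes cut-6 rose 1.70-fold and of 24 patched-related genes ptr-15 fell 1.55-fold, each the only call over all genes and also when adjusted over the list alone. The call of tsp-15 was lost without hs::control replicates 2 or 3 and hs::lin-29 replicates 2 or 3 (adjusted p up to 0.169, range over all alternatives 0.01879 to 0.1689). That of cut-6 was lost without hs::control replicates 2 or 3 and hs::lin-29 replicates 1 or 3 (up to 0.111, range 0.006421 to 0.1107), and that of ptr-15 without hs::control or hs::lin-29 replicate 3 (up to 0.073, range 0.001118 to 0.07304).

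Both strains had the same heat shock, and of 22 heat shock genes 1 rose, hsp-17, by 1.56-fold (log2 fold change 0.64, SE 0.12), the same count as adjusted over the list alone. This call was lost without hs::control replicate 3 (adjusted p 0.0715, range over all alternatives 1.529e-05 to 0.0715). The summed CPM of the 22 genes differed within each strain, from 23040 to 33903 in hs::control and from 21581 to 30251 in hs::lin-29. The highest value was in hs::control replicate 1, the library that stood apart on the second principal component. Of the same list, hsp-16.1, hsp-16.11, hsp-16.48, hsp-16.49, F44E5.4, F44E5.5, hsp-25 and unc-23 are listed at 0 in every library. A listed 0 is not read as absence, so the response of these genes to heat was not measured. Whether the heat response was equal in the strains is not decided by the 22 genes tested.

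Genes of defence and detoxification went both ways. Of 184 immune effector genes 6 rose and 7 fell, the same as adjusted over the list alone. This is close to the 6.60% that passed over all tested genes. clec-55 (4.87-fold), clec-232 (4.27-fold) and clec-144 (3.61-fold) were higher and clec-218 (3.05-fold) lower. Levels were low for clec-55, at 0.350 ± 0.208 and 1.69 ± 0.574 CPM in hs::control and hs::lin-29. Those of clec-232 were 0.626 ± 0.116 and 2.69 ± 0.424 CPM. The call of clec-55 was lost without hs::control replicates 2 or 3 and hs::lin-29 replicates 1 or 3 (adjusted p up to 0.107, range over all alternatives 0.001091 to 0.1072). Of 153 detoxification genes 5 rose and 13 fell, and 8 and 17 adjusted over the list alone. The largest changes among those with a mean of at least 1 CPM were falls, of ugt-63 (4.30-fold), ugt-18 (3.82-fold), ugt-25 (3.81-fold) and cyp-13A10 (3.65-fold). The 5 that rose, named after their values were seen, were cyp-43A1, cyp-33C3, ugt-54, ugt-1 and gst-42, by 1.33-fold to 2.38-fold. Of 6 genes of the intracellular pathogen response none passed over all genes and 1 was lower adjusted over the list alone, with log2 fold changes of -0.75 for skr-4 and -0.43 for cul-6. At an unadjusted p of 0.05 in edgeR 2 of the 6 passed, limma-voom called none and DESeq2 called 1. skr-4 passed with DESeq2 (adjusted p 0.02081), with no filter (0.005598) and without hs::control replicate 3 (0.04381), in a range up to 0.2248.

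Of 92 neuropeptide genes ins-37 rose 5.65-fold, and nlp-30 and nlp-31, which the antimicrobial list also holds, fell; the counts adjusted over the list alone were equal. In 38 cell cycle genes bub-1 rose 1.54-fold, in 34 genes of vulva, uterus and anchor cell lin-1 fell 1.51-fold and in 16 genes of lipid binding lbp-5 fell 1.36-fold, with equal counts adjusted over each list alone. Of 21 histone genes his-59 (1.87-fold) and his-60 (1.80-fold) rose and his-32 fell 2.06-fold, again with equal counts. The call of lbp-5 was lost without hs::control replicates 2 or 3 and hs::lin-29 replicates 2 or 3 (adjusted p up to 0.0642, range over all alternatives 0.0004896 to 0.08616), that of his-59 without any 1 of the 6 libraries (up to 0.171, range 0.01708 to 0.1707), that of his-32 without any but hs::control replicate 1 (up to 0.163, range 0.02387 to 0.1632) and that of his-60 without hs::control replicates 2 or 3 and hs::lin-29 replicates 1 or 2 (up to 0.129, range 0.00229 to 0.1285). Reads shared between near-identical histone copies are left out by such counting, which makes these counts uncertain.

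Markers of other tissues showed few calls. No member passed over all genes or adjusted over the list alone among 20 neuron markers (mec-12 and mec-7 at log2 fold changes of 0.22 and 0.21), 14 muscle markers (unc-52 0.31, tni-3 0.14), 31 germline markers (syp-3 0.58, puf-5 0.61), 72 ribosomal protein genes (rla-1 0.16, rps-29 0.17) and 7 yolk genes (rme-2 0.55, vit-1 -0.38). At an unadjusted p of 0.05 in edgeR, 3 germline markers and 1 yolk gene passed and none of the neuron, muscle and ribosomal genes, and DESeq2 and limma-voom called none of the 5 lists' genes. All 20 neuron markers and 26 of the 31 germline markers had a log2 fold change above 0, and camera gave adjusted p of 0.07533 and 0.06067 and, with an estimated correlation, p = 0.423 and p = 0.506. The neuron list passed camera with no filter (0.02976) and without hs::control replicate 2 (0.04292), hs::control replicate 3 (0.004739) or hs::lin-29 replicate 2 (0.02914), in a range over the alternatives of 0.004739 to 0.6757. The germline list passed, among other alternatives, with library totals only (0.0451), with no filter (0.01031), with a CPM filter (0.04532) and without hs::control replicate 1 (0.0005374), hs::lin-29 replicate 1 (0.02468) or hs::lin-29 replicate 2 (0.001126), in a range of 0.0005374 to 0.5472. syp-3 passed without hs::control replicate 1 (adjusted p 0.03519, in a range up to 0.3458). Of 17 pharynx markers abu-1 rose 3.59-fold, also adjusted over the list alone, a call lost without any of the 3 hs::control libraries (adjusted p up to 0.0593, range over all alternatives 2.249e-07 to 0.1941). Of the intestine markers, 1 rose and 3 fell adjusted over the list alone; elt-2 went from 12.7 ± 2.36 to 34.2 ± 6.97 CPM. Only 2 of 58 sperm genes had counts enough to test, spe-9 and fog-3, at log2 fold changes of 0.07 and -0.01, and neither passed at an unadjusted p of 0.05 in edgeR, in DESeq2 or in limma-voom.

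Of 18 genes often used in transgenes, lin-29 and elt-2 rose and sur-5 fell 1.39-fold, with equal counts adjusted over the list alone. The call of sur-5 was lost without 5 of the 6 libraries, all but hs::control replicate 2 (adjusted p up to 0.105, range over all alternatives 0.003068 to 0.1048). The labels do not describe the transgenes of either strain beyond their names, so a difference in a marker gene and one in the chromosomal gene are not separated.

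By camera, 4 of 31 lists passed an adjusted p of 0.05, the cuticle collagens, the stage collagens, the fatty acid synthesis genes and the epidermal antimicrobial genes. The same test called 5 to 13 lists in every other split of the libraries into equal groups. Each of those splits mixes the strains, so part of a strain difference remains in it and part adds to the spread. Even so, more lists passed there than in the real split. A pass by camera at a correlation of 0.01 is therefore not by itself evidence of a strain difference. With an estimated correlation none of the 31 passed, with an adjusted p of 0.9351 for each, where 1 list, the stage collagens, had p = 0.0385. For the heterochronic, collagen processing, Wnt, lipid binding, immune effector and pharynx lists the median and the mean log2 fold change differ in sign, and none of these 6 passed. The count of lists was 8 without hs::control replicate 2 and 7 without hs::control replicate 3. Besides the neuron, germline and intestine markers, 7 lists passed camera with 1 library left out. These were the cell cycle genes without hs::control replicate 1 (adjusted p 0.00713, range over all alternatives 0.00713 to 0.8156) and the ribosomal protein genes without hs::control replicate 1 (0.001956) or hs::lin-29 replicate 1 (0.001349, range 0.001349 to 0.9865). Without hs::control replicate 2 the neuropeptide genes (range 0.03341 to 0.9001), the histone genes (0.03006 to 0.4669) and the patched-related genes (0.03006 to 0.3719) passed, each at the lowest value of its range. The cuticlin list passed without hs::control replicate 3 (0.01128, range 0.01128 to 0.3461) and the furrow collagens without hs::lin-29 replicate 3 (0.04491, range 0.04491 to 0.9001).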

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

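The alternatives below were chosen before the data were examined, except the counts for single gene lists, which were added afterwards. Across scalings, filters, DESeq2, limma-voom, the test without robust estimation and the 20 most abundant genes left out, between 780 and 1151 genes passed (861 in the reported fit), and all genes that passed in both kept their direction. Leaving out 1 library gave 459 to 894 genes, 135 to 327 higher, 324 to 567 lower, 307 to 477 at 2-fold or more, 5 to 8 gene lists and a log2 fold change of lin-29 of 2.34 to 3.19. Fewer libraries leave fewer degrees of freedom. Without a filter on low counts lin-29 had a log2 fold change of 2.83 and an adjusted p of 0.1017, against a lowest of 8.161e-06 over its alternatives; the cause was not tested. With the estimated correlation 0 lists passed and with fry 1 list.

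With the replicate number as a block, 556 genes passed, 206 higher and 350 lower, and 5 gene lists, the germline markers among them (camera adjusted p 0.03401, higher; range over the alternatives 0.0005374 to 0.5472). Deviations of same-numbered libraries correlated at 0.0112, -0.361 and 0.238, and hs::control replicate 1 correlated best with hs::lin-29 replicate 2 (0.371), so the numbers are not taken to pair the libraries.

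The counts for the added lists moved by over 1.5 times in 3 cases: 7 cuticle collagens lower with DESeq2, 8 without hs::lin-29 replicate 1, and 2 epidermal antimicrobial genes lower without hs::lin-29 replicate 2. Cuticle collagens that rose numbered 27 to 45 over all alternatives.

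For the 98 named genes, 1450 values kept direction and side of the threshold, 91 lost the threshold, 8 gained it and 19 changed sign. All 19 belong to 8 genes that did not pass in the reported fit, with log2 fold changes near 0. fog-3 was at 0.012 with upper-quartile factors and 0.011 with no filter. With 1 library left out the values ran from -0.2015 to 0.0946 for fog-3, -0.0804 to 0.2112 for spe-9, -0.2031 to 0.0614 for sqt-1, -0.237 to 0.0634 for alg-1, -0.0938 to 0.0149 for lin-59, -0.0775 to 0.1689 for lin-14, -0.1875 to 0.0062 for blmp-1 and -0.2087 to 0.0234 for lin-41; the cause was not tested. At 14553652 to 17303509 counts per library the simulated test recovered 36% of 1.5-fold changes, so changes of that size can be missed.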

Other observations

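The counts of the reported fit and camera on the fixed lists under the alternatives were planned. All other tests in this part were chosen after related results had been seen. The bounds for the molt cycle, the intestine and the msp genes were set after the gene lists had been read. Genes were also grouped by the letters of their names, with 246 families of at least 5 tested genes per direction. By Fisher's exact test 6 families held more called genes than chance. The test takes genes as independent, and correlation between members of a family was not tested, so its p-values may be too small. The col and bli families are on the collagen list, and the other 4 bear on the hypothesis that families without a fixed list move together. Among the rises this was the nspb family, 5 of 7 genes (adjusted p 2.17e-05), nspb-6, nspb-7, nspb-8, nspb-9 and nspb-10, with log2 fold changes of 1.43 to 3.06. nspb-8 went from 4.16 ± 0.538 to 23.7 ± 13.5 CPM. Whether these genes are similar enough for reads to be lost or shared between them was not tested, and the nspb genes were named after their values were seen.

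Among the falls the fbxa family of F-box genes led, with 21 of 110 genes lower (adjusted p 9.118e-07). fbxa-128 fell 4.18-fold, from 13.9 ± 1.25 to 3.32 ± 0.197 CPM, and fbxa-60 2.49-fold, while fbxa-23 rose 2.43-fold. The math family, with a MATH domain as in many ubiquitin ligase adaptors, had 6 of 24 genes lower (adjusted p 0.02853), among them math-20, 3.82-fold lower at 8.07 ± 2.03 CPM, and math-44 rose. Peroxin genes, which build peroxisomes, had 5 of 10 lower (adjusted p 0.003111): prx-11 fell 4.29-fold, prx-1 2.36-fold, prx-5 1.87-fold, prx-12 1.49-fold and prx-13 1.46-fold. In the fixed list of fatty acid breakdown, the genes of the peroxisomal pathway daf-22 and dhs-28 fell 1.47-fold and 1.37-fold. The genes in this paragraph other than prx-11 were named after their values were seen.

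The rise of cuticle collagens, bli-1, bli-2 and col-19 among them, may come from LIN-29 itself, from other differences between the strains or from a difference in developmental timing. A different phase of the larval molt cycle as the whole cause was set against the 31 furrow collagen and molting genes. Of these 3.23% passed, against 6.60% of all tested genes. Their log2 fold changes ran from -0.54 to 0.58, with a median of -0.09. The collagens that rose had a median rise of 19.1-fold, but they were picked because they rose. Over all 140 cuticle collagens tested the median log2 fold change was 0.26, inside that range, so the gap cannot decide the question. The low share cannot decide it either. Before adjustment, edgeR's p was under the same threshold for 6 of 26 molting genes and 0 of 5 furrow collagens. It was so for 2372 of all 13045 tested genes, so the set was not clearly depleted. The summed furrow collagens also differed within hs::lin-29, at 944, 1286 and 1555 CPM in replicates 1 to 3. The 5 furrow collagens passed camera (lower) without hs::lin-29 replicate 3 (adjusted p 0.04491, range over the alternatives 0.04491 to 0.9001). A different phase therefore stays open. Whether L4 animals with spermatogenesis were present is not decided by the msp genes: their summed CPM was 1.22 ± 0.212 in hs::control and 1.54 ± 0.615 in hs::lin-29, a ratio of 1.26 (two-sided exact permutation p = 0.7, where 0.1 is the smallest 3 against 3 can give), from 17 to 37 counts per library over 30 genes, and a minimum count for reading it was added after the counts were seen, without which this ratio would have counted against L4 animals. LIN-29 and the other strain differences stay open, as both are tied to the groups. In hs::lin-29 replicates 1 to 3 lin-29 stood at 131, 517 and 339 CPM. The summed cuticle collagens stood at 82145, 65354 and 73051 CPM, in the opposite order. Not every collagen followed that order, as bli-1 stood at 194, 234 and 379 CPM, and 3 libraries are too few to decide on a relation.

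The falls of nhr-80, elo-5, elo-6 and other lipid and peroxisome genes, 16 of 50 tested, were set against a lower share of intestinal RNA in hs::lin-29, which could lower intestinal genes together. Over 20 intestine markers, 15 of them below 0, the median log2 fold change was -0.12 (quartiles -0.29 and -0.02). It lay 0.87 above that of the 16 genes, and 3 markers fell as far. The 16 were picked because they fell, so their median had to be low and this gap cannot decide the question. Counted over all genes of each set, 16 of the 50 and 3 of the 20 markers lay below the markers' lower quartile by over 2 SE. Few markers can lie below a bound taken from their own values, so these counts cannot be compared. Over all 50 the median was -0.25 (quartiles -0.71 and 0.02), 0.13 below the markers and within their interquartile range of 0.27. The markers passed camera (lower) without hs::control replicate 3 (adjusted p 0.01128, range over the alternatives 0.01128 to 0.6493). With an estimated correlation over all libraries camera gave them p = 0.416. A lower share of intestinal RNA, as the whole or a part of the change, therefore stays open. A response of these genes to LIN-29, a strain difference and a change of state within the intestine also stay open and were not tested.

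Another pattern concerns the tables: 1954 of 17365 coding genes are listed at 0 in every library, among them the collagen gene sqt-3, the muscle genes unc-15 and lev-11 and the ribosomal protein genes rpl-1, rpl-29, rpl-30, rpl-31, rpl-32 and rps-6. That 6 ribosomal protein genes are at 0 argues against lack of transcription as the whole cause, and 38.4% of the genes at 0 overlap another gene against 37.8% of the rest, which argues against overlap as the whole cause. The share at 0 is 27.8% for genes with at least 2 annotated transcripts and far lower for genes with 1 (483 of 12082), a ratio of 6.97 (odds ratio 9.27), consistent with counting that discards reads shared by several transcripts of a gene. Most genes with several transcripts do have counts: 1471 of 5283 coding genes with at least 2 are at 0, and 6 of 28 such ribosomal protein genes. Several transcripts alone therefore do not account for a 0. If reads are discarded in this way, counts of other genes with several transcripts, such as lin-29 with 3, may cover only part of the gene. Which step of the processing does this was not tested.

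With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 861 genes, 321 higher, 540 lower and 434 at 2-fold or more, each of which 1 of the 10 splits reached, the real one; the highest of the others was 0 in each case by edgeR. In those 9 splits 123 to 1423 genes had an unadjusted p under 0.05, DESeq2 called 0 to 109 and limma-voom 0. Those splits mix the strains, so a strain difference adds to the spread within their groups and can lower such counts. For gene lists the real split gave 4, the fewest of all 10 splits, and the other 9 gave 5 to 13. The 13 lists came from the split that sets hs::control replicates 1 and 3 with hs::lin-29 replicate 2 against the rest, so the libraries hold structure besides strain.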
